A study of Mus musculus with 36 samples.

How the data were processed

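Gene expression was measured by mRNA sequencing of intestinal organoids. Per the labels, 36 libraries came from 2 organoid cultures, each from 1 of 2 male wild-type C57BL/6 littermates, with RNA purified in duplicate for each of 9 conditions: before treatment (0 h), and 6 h and 24 h with DMSO, atRA (10 µM), 9cisRA (10 µM) or an RXR antagonist (5 µM). Single cells were grown for 3 days in medium with Wnt3a-conditioned medium, a ROCK inhibitor and a GSK3 inhibitor, and treatment began with the change to medium without these, per the labels. Each condition thus had 4 libraries but n = 2 mice.

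The values analysed were RPKM (reads per kilobase of gene, scaled to library size) as deposited by the authors, for 12652 genes, and the reads behind them were counted upstream. The submitters' processing notes name bcl2fastq 2.17, STAR 2.5.2b and the genome build mm10, with no further detail of counting. How the per-library divisor was set is not stated, so it was worked out from the table. Whole reads and gene lengths could be recovered for 100% of the genes (tolerance 0.05 reads). The divisor, 20.5 to 30.3 M reads, followed a median-of-ratios size factor (SD of the log ratio 0.652%) rather than the sum of recovered reads (5.58%). Recovered reads per library summed to 19.6 to 30.7 M reads, a ratio of 1.56, over the listed genes. At this depth 1 read of a 2000-base gene equals 0.0165 to 0.0244 RPKM. Values of 0 made up 0.136% of the table (618 values in 160 genes). Duplicates correlated at r = 0.995 to 0.998 across genes, and the 2 mice of a condition, compared at duplicate 1, at 0.994 to 0.997. None of these pairs was identical. The chi-square of reads per degree of freedom, near 1 for counting noise alone, was 3.21 to 16.0 between duplicates. Between mice it was 5.94 to 25.6, so the ranges overlapped and duplicates differed by more than counting noise. Gene positions are those of GENCODE M21 on GRCm38 (mm10), matched by Entrez gene identifier.

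Genes with RPKM of at least 1 in at least 4 of the 36 libraries were tested (11361 genes). Values were taken as log2(RPKM + 0.5), and the 2 duplicates of each mouse and condition were averaged, giving 18 values. One limma model (limma 3.58.1 under R 4.3.3) with a mean per condition and the mouse as a block was fitted with an intensity trend in the variance prior (8 residual and 5.01 prior degrees of freedom), and 14 comparisons were tested: each compound against DMSO at each time, the isomers against each other at each time, the DMSO series (3 pairs of times) and the change of each compound's effect between 6 h and 24 h. Benjamini-Hochberg adjustment ran over the tested genes within a comparison, two-sided, with calls at an adjusted p below 0.05. Intervals are 95% intervals. The mouse served as a block because the labels name the animal. The differences between mice correlated between conditions with a median of 0.441 (0.0372 to 0.662). Those between duplicate numbers had a median of -0.011 and ranged from -0.412 to 0.541. Duplicate numbers thus showed no common pairing, although some pairs of conditions correlated.

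Of 36 gene lists, written from general knowledge before the data were examined, 27 had at least 5 tested members. These were tested in all 14 comparisons (378 tests) with camera from limma at a preset correlation of 0.01, beside camera with an estimated correlation and the self-contained test fry, adjusted over lists within a comparison. Camera made 163 calls, of which 28 held with an estimated correlation, and fry made 210. Counts adjusted over the list alone use the p of the list's members only. Overlaps between compounds were set against independent lists, against 100 simulated draws of unchanged groups that share the DMSO values, and against DMSO libraries split between the compounds.

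Sample groups, tests, alternatives, gene lists and the rule for named genes were fixed before the data were examined. Named genes are the 6 highest and 6 lowest of each compound against DMSO (5 and 5 in the other comparisons) among called genes with an absolute log2 fold change of at least 1, the same sign in both mice and a mean of at least 1 RPKM in 1 of the groups, then up to 4 members with the smallest p of each list described, and a fixed panel of retinoid, stem cell, differentiation and lipid genes. The alternatives changed the pseudocount (0.1 and 1), the filter (none, or a mean of at least 5 RPKM), the scaling (median-of-ratios factors, quantile normalization), the treatment of duplicates and mouse, the variance prior, the groups in the fit, the thresholds, the set test and the DMSO libraries, and left out each library and each mouse in turn. Fits without a mouse took the duplicate libraries of the other mouse as samples. Their spread is thus that between duplicates of 1 culture, and not between mice as in the main fit. Scaling to read sums, voom on recovered reads, fits of treatment by mouse and the exchange of the split DMSO libraries were added after the data were seen. Other splits of the samples were not counted, since n = 2 mice per condition leaves just 2 exchanges of labels within mice.

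The test was tried on simulated data shaped like atRA against DMSO at 24 h, where it recovered 83% of genes changed by 0.5 on the log2 scale and 97% of those changed by 1, with 11 false calls (5.76% of calls). It made 0 calls by limma in a comparison with nothing changed. The simulation changed 100 genes by 0.5 and 100 by 1, in both directions, with noise drawn independently for each gene. The real comparison called 38.0% of the tested genes, and shifts shared by many genes were not simulated. These rates may therefore not carry over to the real libraries. Figures were drawn with matplotlib 3.10.9 and numpy 2.4.6 in Python 3.11.15. Genes with near-identical relatives were kept with the uncertainty stated, and genes below the filter were left out because their log2 values rest on few reads. Results of a few single genes are not reported here, although these genes stay in the fits, totals and lists.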

Results

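Intestinal organoids from 2 male wild-type mice were sequenced before treatment (0 h) and at 6 h and 24 h with vehicle (DMSO), all-trans retinoic acid (atRA, 10 µM), its 9-cis isomer (9cisRA, 10 µM) or an RXR antagonist (RXRi, 5 µM). Treatment began with the change from medium with a Wnt source, a ROCK inhibitor and a GSK3 inhibitor to medium without them. The cultures at 0 h had no DMSO, so changes from 0 h cannot be split among vehicle, medium change and time. The questions were what each compound changed against vehicle at the same time, whether the isomers differed, and what vehicle cultures did over time. Log2 fold changes are given ± SE on the scale of log2(RPKM + 0.5), which understates changes of genes with low RPKM, and RPKM levels are means ± SD over n = 2 mice. Of 12652 genes, 11361 were tested. Every named gene said to rise or fall did so in both mice. In a principal component analysis of the tested genes, the first component held 60.1% of the variance, the second 19.8% and the third 8.16%.

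**Figure D1:**
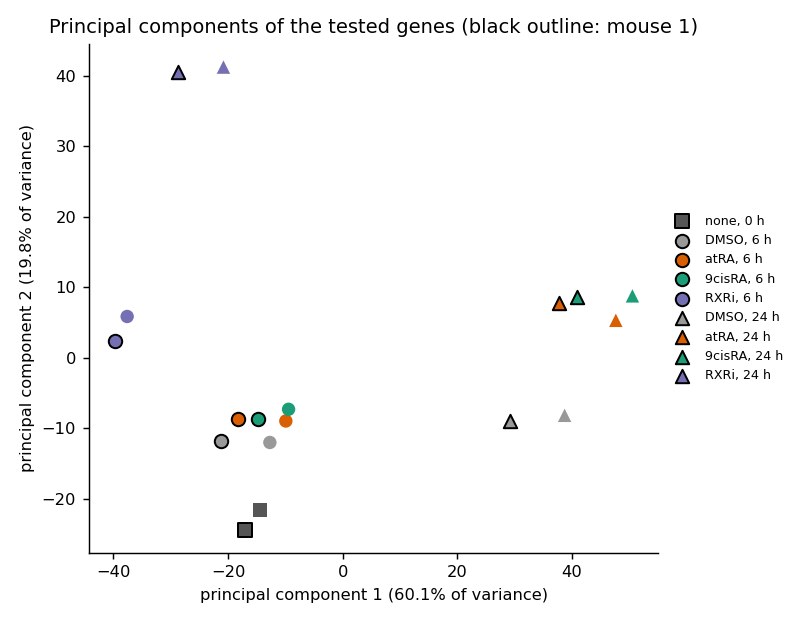
Principal components over 11361 tested genes, with 60.1% of the variance on the first axis and 19.8% on the second. Each point is the mean of the 2 duplicate libraries of a mouse and condition, with shapes for times, colors for compounds and a black outline for mouse 1.

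With vehicle alone, enterocyte transcripts rose over 24 h while transcripts of dividing cells fell. Apoa4, an apolipoprotein of absorptive cells (chromosome 9, 46240696 to 46243459, GRCm38), was 4.89 ± 0.23 log2 higher at 24 h than at 0 h (653 ± 188 against 21.3 ± 0.846 RPKM, adjusted p = 2.15e-09), and Sis, the sucrase-isomaltase of the brush border, 3.94 ± 0.18 higher (adjusted p = 2.42e-09). Reg3a and Reg1, secreted lectin family members, rose by 5.71 ± 0.29 and 5.34 ± 0.16, and Adh1 and Rdh7, enzymes that oxidize alcohols including retinol, by 4.93 ± 0.17 and 4.70 ± 0.24. Muc2, the main goblet cell mucin, rose by 2.35 ± 0.11 and the Paneth cell lysozyme Lyz1 by 1.05 ± 0.20. The proliferation marker Mki67 changed by -0.43 ± 0.066, and the Wnt target Axin2 by -0.86 ± 0.068. All 43 tested enterocyte markers rose (43 higher adjusted over the list alone, median 2.48, camera adjusted p = 1.25e-24, and adjusted p = 0.117 with an estimated correlation). Brush border genes rose at 16 of 17 (16 higher adjusted over the list alone, camera adjusted p = 1.40e-07, and adjusted p = 0.0318 with an estimated correlation). Paneth cell markers rose at 17 and fell at 2 of 20 (17 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.000593, and adjusted p = 0.327 with an estimated correlation). Goblet cell markers rose at 16 and fell at 2 of 20 (16 higher and 2 lower adjusted over the list alone, camera adjusted p = 8.25e-05, and adjusted p = 0.226 with an estimated correlation). All 35 cell cycle genes fell (35 lower adjusted over the list alone, median -0.50, camera adjusted p = 1.38e-12, and adjusted p = 0.117 with an estimated correlation). Wnt target genes fell at 11 of 12 (11 lower adjusted over the list alone, camera adjusted p = 7.89e-05, and adjusted p = 0.117 with an estimated correlation). The limma test called 3317 genes higher and 3437 lower, 572 of them by at least 2-fold (553 higher and 19 lower). Quantile normalization gave 2681 and 4385, and scaling to each library's read sum 2547 and 4559.

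The first 6 h in vehicle brought lower Wnt target transcripts and lower Cyp1a1 and Cyp1b1. Cyp1a1, a xenobiotic-metabolizing cytochrome P450 (chromosome 9, 57687928 to 57703824), fell by 2.92 ± 0.11 on the log2 scale (1.53 ± 0.0587 against 14.9 ± 2.54 RPKM, adjusted p = 5.68e-09), with Cyp1b1 at -2.06 ± 0.15 and Ahrr, a repressor of the aryl hydrocarbon receptor, at -1.22 ± 0.092. Ascl2, a transcription factor of intestinal stem cells, changed by -1.12 ± 0.15 (adjusted p = 5.67e-05) and Axin2 by -1.01 ± 0.068 (adjusted p = 4.08e-07). Acsbg1, an acyl-CoA synthetase, rose by 1.93 ± 0.11, Cavin3, a caveola protein, by 1.69 ± 0.12 and Mxd1, a partner of Max that antagonizes Myc, by 1.49 ± 0.047. Wnt target genes fell at 9 of 12 (9 lower adjusted over the list alone, camera adjusted p = 0.000494, and adjusted p = 0.209 with an estimated correlation). Stem cell markers fell at 12 of 19 (12 lower adjusted over the list alone, camera adjusted p = 0.000343, and adjusted p = 0.115 with an estimated correlation). Immediate early genes rose at 12 of 17 (12 higher adjusted over the list alone, camera adjusted p = 0.000151, and adjusted p = 0.209 with an estimated correlation). In all, 2537 genes rose and 2657 fell, 78 by at least 2-fold (63 up, 15 down). Read-sum scaling gave 2188 and 3182.

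Between 6 h and 24 h in vehicle, Reg1 rose by 5.79 ± 0.16, Reg3a by 5.09 ± 0.29 and Zg16, a goblet cell lectin, by 4.49 ± 0.24. Gcg and Cck, which encode gut peptide hormones, changed by -1.49 ± 0.21 (adjusted p = 4.95e-05) and -1.70 ± 0.18 (adjusted p = 4.08e-06), and Acsbg1 by -1.51 ± 0.11. Of 43 enterocyte markers, 42 rose (42 higher adjusted over the list alone, camera adjusted p = 9.74e-27, and adjusted p = 0.0944 with an estimated correlation). Enteroendocrine markers as a list were not called here (median -0.29, camera adjusted p = 0.123). The test called 2882 genes higher and 2785 lower, 571 by at least 2-fold (516 higher, 55 lower). With quantile normalization the split was 2323 and 3933, and with read-sum scaling 2376 and 3662.

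At 6 h, atRA raised a small set of genes, led by Gkn3, Cym and Fgf15. Gkn3, a gastrokine, rose by 2.12 ± 0.19 (8.67 ± 0.260 against 1.62 ± 0.367 RPKM, adjusted p = 3.68e-05) and Cym, the protease chymosin, by 2.04 ± 0.29 (adjusted p = 0.00147). Fgf15, the gut hormone that represses bile acid synthesis (chromosome 7, 144896531 to 144900953), rose by 1.66 ± 0.11 (18.3 ± 2.71 against 5.46 ± 1.02 RPKM, adjusted p = 4.76e-06). Slc51b, a subunit of the basolateral bile acid exporter, rose by 1.57 ± 0.24 (adjusted p = 0.00200). Ivl and Sprr1a, components of the cornified envelope, rose by 1.58 ± 0.17 and 1.40 ± 0.12, although the similarity of Sprr genes makes their read assignment uncertain. Fmo5, a flavin monooxygenase, rose by 1.53 ± 0.12, and Pdk4, a kinase that inhibits pyruvate dehydrogenase, by 1.24 ± 0.075. Among retinoid genes, Dhrs3, a retinaldehyde reductase (chromosome 4, 144892827 to 144928209), rose by 1.08 ± 0.10 (21.2 ± 0.377 against 9.81 ± 1.13 RPKM, adjusted p = 3.68e-05) and Isx, a homeobox repressor of carotenoid cleavage, by 0.60 ± 0.10. Cyp26b1, which degrades retinoic acid, rose by 0.65 ± 0.12 (adjusted p = 0.00768) at 0.338 ± 0.0211 RPKM, a call that a pseudocount of 1 ended (0.37, adjusted p = 0.0519). Without the mouse block, the call of Isx ended (adjusted p = 0.182).

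As groups at 6 h with atRA, 5 of 12 retinoic acid response genes rose and none fell (6 higher and 1 lower adjusted over the list alone, median 0.23, camera adjusted p = 3.61e-06, and adjusted p = 0.0554 with an estimated correlation). PPAR target genes rose at 9 of 28 (14 higher and 1 lower adjusted over the list alone, camera adjusted p = 7.50e-08, and adjusted p = 0.0693 with an estimated correlation). FXR target genes rose at 3 of 7 (5 higher adjusted over the list alone, camera adjusted p = 3.61e-06, and adjusted p = 0.0554 with an estimated correlation). Interferon response genes rose at 6 of 21 (10 higher adjusted over the list alone, camera adjusted p = 1.04e-08, and adjusted p = 0.0693 with an estimated correlation). The test called 317 genes higher and 212 lower, 14 by at least 2-fold, all of these upward. That total of 529 was not stable. It was 229 without mouse 1, 1003 without mouse 2 and 177 without the mouse block. With 1 library left out, it went from 354 without the second atRA library of mouse 2 to 1061 without the first.

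With 9cisRA at 6 h, Pdk4, Acot2 and Abca1 rose beside genes that atRA raised. Pdk4 (chromosome 6, 5483351 to 5496309) rose by 2.82 ± 0.075 (5.04 ± 0.179 against 0.286 ± 0.0404 RPKM, adjusted p = 1.37e-10). Acot2 and Acot1, acyl-CoA thioesterases, rose by 2.10 ± 0.12 and 2.07 ± 0.10, although reads of these near-identical genes cannot be assigned with certainty. Abca1, the cellular cholesterol exporter (chromosome 4, 53030787 to 53159895), rose by 1.42 ± 0.11 (adjusted p = 4.33e-06), and Abcg5, a subunit of the sterol exporter, by 0.99 ± 0.084. Gkn3 rose by 2.60 ± 0.19, Cym by 2.14 ± 0.29, Fgf15 by 1.78 ± 0.11, Dhrs3 by 1.04 ± 0.10 and Isx by 0.69 ± 0.10 (adjusted p = 0.0867 for Isx without the mouse block). Pkp1, a desmosomal plakophilin, fell by 1.17 ± 0.077 (adjusted p = 1.01e-06), and Myc changed by -0.50 ± 0.065 (adjusted p = 0.000299). PPAR target genes rose at 20 of 28 (21 higher adjusted over the list alone, median 0.39, camera adjusted p = 4.75e-22, and adjusted p = 0.00987 with an estimated correlation). LXR target genes rose at 9 of 12 (9 higher adjusted over the list alone, camera adjusted p = 2.20e-10, and adjusted p = 0.0147 with an estimated correlation). Retinoic acid response genes rose at 5 of 12 (7 higher and 1 lower adjusted over the list alone, camera adjusted p = 4.27e-07, and adjusted p = 0.0236 with an estimated correlation). FXR target genes rose at 4 of 7 (5 higher adjusted over the list alone, camera adjusted p = 3.01e-07, and adjusted p = 0.0147 with an estimated correlation). Cholesterol synthesis genes fell at 8 of 25 (15 lower adjusted over the list alone, camera adjusted p = 1.47e-07, and adjusted p = 0.00987 with an estimated correlation). Among them, Msmo1 stood at -0.40 ± 0.064 and Fdft1 at -0.34 ± 0.043. The test called 569 genes higher and 344 lower, 37 by at least 2-fold (36 higher, 1 lower). That total of 913 was 416 without the mouse block, 631 without mouse 1 and 1602 with the 36 libraries as separate samples.

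Set against each other at the same dose and 6 h, the isomers, which differ in the geometry of 1 double bond, differed at genes such as Pdk4 and Abca1, which were higher with 9cisRA. Pdk4 was 1.58 ± 0.075 higher (adjusted p = 2.24e-07) and Abca1 1.205 ± 0.11 (adjusted p = 0.000229). Gdf15, a stress-induced hormone, was 0.87 ± 0.12 higher and Cpt1a, which admits fatty acids to mitochondria, 0.55 ± 0.050. PPAR target genes were higher with 9cisRA at 11 of 28 (18 higher adjusted over the list alone, camera adjusted p = 8.76e-19, and adjusted p = 0.0263 with an estimated correlation). LXR target genes were higher with it at 6 of 12 (9 higher adjusted over the list alone, camera adjusted p = 8.85e-11, and adjusted p = 0.0263 with an estimated correlation). No difference was called for the retinoid genes Dhrs3 (-0.032 ± 0.10, interval -0.24 to 0.17) and Isx (0.083 ± 0.10, -0.14 to 0.30), or for Fgf15 (0.12 ± 0.11, -0.12 to 0.35). The test called 176 genes higher with 9cisRA and 19 lower, 6 by at least 2-fold, all of these higher. That total of 195 ranged with the atRA libraries left out: 95 without the first of mouse 1, 335 without the second of mouse 1, 695 without the first of mouse 2 and 43 without the second of mouse 2. It was 58 without mouse 1, 75 without mouse 2 and 40 without the mouse block.

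By 24 h, atRA had raised Cyp26b1, Fabp6 and Fgf15 and lowered Ctrb1 and Slc13a2. Cyp26b1 (chromosome 6, 84571414 to 84593908) rose by 3.99 ± 0.12 (11.9 ± 1.74 against 0.282 ± 0.104 RPKM, adjusted p = 2.54e-10). Fabp6, the ileal bile acid binding protein (chromosome 11, 43596049 to 43601540), rose by 3.80 ± 0.28 (7.75 ± 4.09 against 0.0579 ± 0.0819 RPKM, adjusted p = 9.28e-07), a size that depends on the pseudocount because DMSO libraries held next to no reads of it. Fgf15 rose by 3.41 ± 0.11, Slc51b by 3.27 ± 0.24, its partner subunit Slc51a by 1.65 ± 0.089 and Nr0b2, a bile acid-induced nuclear receptor without DNA-binding domain, by 2.57 ± 0.13. Pdk4 rose by 3.37 ± 0.075 (7.08 ± 0.491 against 0.235 ± 0.0429 RPKM). Ctrb1, a chymotrypsinogen, fell by 2.13 ± 0.25 (adjusted p = 3.27e-05), and Slc13a2, a citrate and dicarboxylate transporter, fell by 1.89 ± 0.21 (adjusted p = 2.13e-05). Cyp3a11 (a drug-metabolizing P450 with close relatives, so its assignment is uncertain) changed by -1.56 ± 0.25, and the near-identical predicted genes Gm8989 and Gm8979 by -1.55 ± 0.16 and -1.503 ± 0.15. Olfm4, a stem cell zone glycoprotein, fell by 1.18 ± 0.26 (adjusted p = 0.00354, and adjusted p = 0.0712 without the mouse block) and Mki67 fell by 0.65 ± 0.066 (adjusted p = 1.04e-05).

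All 7 tested FXR target genes rose with atRA at 24 h (7 higher adjusted over the list alone, median 2.57, camera adjusted p = 1.66e-08, and adjusted p = 0.0181 with an estimated correlation). Of 28 PPAR target genes, 24 rose (24 higher adjusted over the list alone, camera adjusted p = 1.91e-18, and adjusted p = 0.0181 with an estimated correlation). Retinoic acid response genes rose at 8 and fell at 1 of 12 (8 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.000197, and adjusted p = 0.0620 with an estimated correlation). Cell cycle genes fell at 34 of 35 (34 lower adjusted over the list alone, median -0.52, camera adjusted p = 1.25e-19, and adjusted p = 0.0515 with an estimated correlation). Interferon response genes rose at 17 of 21 (17 higher and 1 lower adjusted over the list alone, camera adjusted p = 3.56e-09, and adjusted p = 0.0515 with an estimated correlation). Enterocyte markers went both ways, 11 higher and 15 lower of 43 (12 higher and 17 lower adjusted over the list alone, camera adjusted p = 0.683, and adjusted p = 0.882 with an estimated correlation). In all, 2203 genes rose and 2111 fell, 118 by at least 2-fold (88 up, 30 down). With quantile normalization the split was 2022 and 2262, and with read-sum scaling 1329 and 3549.

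After 24 h with 9cisRA, Pdk4, Cyp4a10 and Acacb were among the genes that rose most. Pdk4 rose by 4.32 ± 0.075 (14.2 ± 1.26 against 0.235 ± 0.0429 RPKM, adjusted p = 5.44e-13) and Acacb, the acetyl-CoA carboxylase that limits mitochondrial fatty acid entry, by 3.26 ± 0.10. Cyp4a10, a fatty acid omega-hydroxylase with near-identical relatives that make its assignment uncertain, rose by 3.79 ± 0.25. Scd1, a fatty acid desaturase, rose by 1.98 ± 0.10 and Abca1 by 1.92 ± 0.11, while Cyp26b1 rose by 2.99 ± 0.12 and Fgf15 by 2.96 ± 0.11. Ctrb1 fell by 2.171 ± 0.25, Akr1c14, an aldo-keto reductase, fell by 1.83 ± 0.14, Slc13a2 fell by 1.73 ± 0.21 and Cyp2c29, a P450 of drug and fatty acid metabolism, fell by 1.69 ± 0.16. Olfm4 fell by 1.44 ± 0.26 (adjusted p = 0.000659) and Mki67 fell by 0.74 ± 0.066 (adjusted p = 2.14e-06). PPAR target genes rose at 26 of 28 (26 higher adjusted over the list alone, median 1.01, camera adjusted p = 1.71e-18, and adjusted p = 0.0350 with an estimated correlation). FXR target genes rose at 6 of 7 (6 higher adjusted over the list alone, camera adjusted p = 2.94e-05, and adjusted p = 0.0440 with an estimated correlation). Brush border genes rose at 15 of 17, with 1 lower (15 higher and 1 lower adjusted over the list alone, camera adjusted p = 7.43e-06, and adjusted p = 0.0389 with an estimated correlation). Retinoic acid response genes rose at 10 of 12 (10 higher adjusted over the list alone, camera adjusted p = 0.000101, and adjusted p = 0.0624 with an estimated correlation). Cell cycle genes fell at 34 of 35 (34 lower adjusted over the list alone, camera adjusted p = 1.71e-18, and adjusted p = 0.0567 with an estimated correlation). The test called 2775 genes higher and 2671 lower, 160 by at least 2-fold (122 higher, 38 lower). Quantile normalization gave 2538 and 2890. Read-sum scaling shifted the median of all genes by -0.12 here and gave 1576 and 4589.

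Between the isomers at 24 h, Fabp6 showed the widest gap among called genes, at -3.32 ± 0.28 with 9cisRA relative to atRA (0.284 ± 0.177 against 7.75 ± 4.09 RPKM, adjusted p = 9.11e-05). Cyp26b1 (-1.002 ± 0.12, adjusted p = 0.00261) and Slc51a (-0.67 ± 0.089, adjusted p = 0.00570) were also lower with 9cisRA. Abca1 was 1.37 ± 0.11 higher with 9cisRA (adjusted p = 9.11e-05), Pdk4 0.96 ± 0.075 (adjusted p = 9.11e-05) and Srebf1, a regulator of fatty acid synthesis, 0.75 ± 0.11. Apoa4 was 1.25 ± 0.23 higher (adjusted p = 0.0357), a call that ended with quantile normalization (1.13, adjusted p = 0.0581) and with a robust variance prior (adjusted p = 0.0562). The call of Cyp26b1 ended with a pseudocount of 0.1 (-1.05, adjusted p = 0.0643). Without the mouse block, the calls of Apoa4 (adjusted p = 0.385), Slc51a (0.0559) and Srebf1 (0.0963) ended. FXR target genes were lower with 9cisRA at 3 of 7 (1 higher and 5 lower adjusted over the list alone, camera adjusted p = 1.03e-06, and adjusted p = 0.0185 with an estimated correlation). Cholesterol synthesis genes were lower with it at 5 of 25 (13 lower adjusted over the list alone, camera adjusted p = 4.19e-10, and adjusted p = 0.00608 with an estimated correlation). PPAR target genes were higher at 6 of 28 (18 higher and 1 lower adjusted over the list alone, camera adjusted p = 7.05e-16, and adjusted p = 0.0185 with an estimated correlation). For LXR target genes this held at 3 of 12 (7 higher adjusted over the list alone, camera adjusted p = 7.33e-07, and adjusted p = 0.0417 with an estimated correlation). No difference was called for Dhrs3 (-0.025 ± 0.10, interval -0.23 to 0.18), Isx (-0.016 ± 0.10, -0.24 to 0.21) or Slc51b (-1.10 ± 0.24, -1.61 to -0.60), and these intervals are not adjusted for the number of genes. Just 34 genes were called higher with 9cisRA and 19 lower, 4 of these by at least 2-fold (Abca1, Apoa4, Fabp6 and Cyp26b1). With read-sum scaling they were 23 and 28. In all, 10 genes were called without the mouse block, 112 without mouse 1 and 84 without mouse 2.

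**Figure D2:**
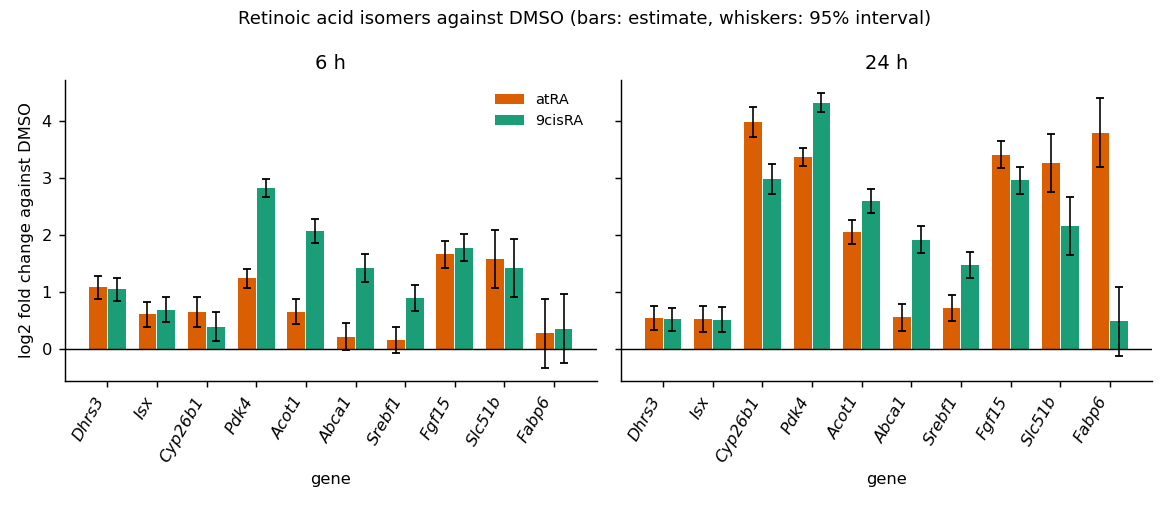
Log2 fold changes of 10 genes against DMSO for atRA and 9cisRA, at 6 h (left) and 24 h (right), from 2 mice. Bars are estimates, whiskers 95% intervals, and Fabp6 rose by 3.80 with atRA at 24 h.

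The retinoic acid effects grew between 6 h and 24 h at Cyp26b1 and at PPAR target genes. For atRA, the effect at 24 h exceeded that at 6 h by 3.34 ± 0.17 at Cyp26b1 (adjusted p = 3.09e-07) and 2.74 ± 0.35 at Cyp4a10. At 6 h Cyp26b1 lay below 0.5 RPKM with atRA and with DMSO. There the pseudocount of 0.5 understates its change, so part of the excess at Cyp26b1 comes from the pseudocount. For 9cisRA the excess was 3.40 ± 0.35 at Cyp4a10, 2.60 ± 0.17 at Cyp26b1 (adjusted p = 7.08e-06) and 1.94 ± 0.14 at Acacb. Ctrb1 moved the other way, by -1.90 ± 0.35 with atRA and -2.13 ± 0.35 with 9cisRA, and the atRA effect on Dhrs3 shrank (-0.54 ± 0.13, adjusted p = 0.0184), a call that ended without mouse 1 (-0.44, adjusted p = 0.0799) and without the mouse block (adjusted p = 0.153). PPAR target genes had larger effects at 24 h at 22 of 28 with atRA (25 higher adjusted over the list alone, camera adjusted p = 2.85e-17, and adjusted p = 0.02002 with an estimated correlation). With 9cisRA this held for 20 of 28 (24 higher adjusted over the list alone, camera adjusted p = 2.04e-14, and adjusted p = 0.0386 with an estimated correlation). FXR target genes had larger effects at 24 h at 6 of 7 with atRA (7 higher adjusted over the list alone, camera adjusted p = 1.37e-07, and adjusted p = 0.02002 with an estimated correlation) and at 4 of 7 with 9cisRA (4 higher adjusted over the list alone, camera adjusted p = 0.00131, and adjusted p = 0.110 with an estimated correlation). Cell cycle genes had lower effects at 24 h at 31 of 35 with atRA (33 lower adjusted over the list alone, camera adjusted p = 2.02e-21, and adjusted p = 0.0372 with an estimated correlation). With 9cisRA they were 33 of 35 (33 lower adjusted over the list alone, camera adjusted p = 1.78e-24, and adjusted p = 0.0432 with an estimated correlation). The effect of atRA differed between times at 1947 genes (1139 higher at 24 h, 808 lower) and that of 9cisRA at 2040 (1142 and 898). These totals were 635 and 1147 without mouse 1, and 983 and 1073 without the mouse block. With 1 library left out they ran from 1319 to 2424 for atRA and from 1663 to 2455 for 9cisRA. Quantile normalization gave 874 and 938 for atRA and 923 and 937 for 9cisRA. Read-sum scaling gave 571 and 1707 for atRA and 557 and 2222 for 9cisRA, where it shifted the median by -0.11.

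With the RXR antagonist at 6 h, Cyp1a1 and Cyp1b1 rose and enterocyte genes fell. Cyp1a1 rose by 4.19 ± 0.11 (36.6 ± 0.660 against 1.53 ± 0.0587 RPKM, adjusted p = 5.33e-11), Cyp1b1 by 2.70 ± 0.15, Ahrr by 2.24 ± 0.092 and Tiparp, a poly(ADP-ribose) polymerase family member, by 1.94 ± 0.082. The water and glycerol channel Aqp3 rose by 2.21 ± 0.16. Trim31, a ubiquitin ligase (chromosome 17, 36898118 to 36910214), fell by 3.11 ± 0.094 (1.64 ± 0.0887 against 18.03 ± 1.60 RPKM, adjusted p = 1.71e-10), Ms4a18 fell by 2.89 ± 0.13 and Clrn3 fell by 2.76 ± 0.093. Apoa4 fell by 2.25 ± 0.23 (adjusted p = 7.07e-06), Apoa1 fell by 2.15 ± 0.29 and Sis fell by 1.30 ± 0.18 (adjusted p = 0.0673 for Sis without the mouse block). The retinoid genes Isx and Dhrs3 changed by -1.49 ± 0.10 (adjusted p = 2.43e-07) and -0.95 ± 0.10 (adjusted p = 7.21e-06), yet Pdk4 rose by 0.997 ± 0.075. Enterocyte markers fell at 36 and rose at 1 of 43 (1 higher and 37 lower adjusted over the list alone, median -0.94, camera adjusted p = 4.30e-18, and adjusted p = 0.184 with an estimated correlation). Brush border genes fell at 16 and rose at 1 of 17 (1 higher and 16 lower adjusted over the list alone, camera adjusted p = 4.02e-12, and adjusted p = 0.00568 with an estimated correlation). LXR target genes fell at 10 of 12 (10 lower adjusted over the list alone, camera adjusted p = 4.63e-07, and adjusted p = 0.0963 with an estimated correlation). Genes of retinoid uptake, storage and synthesis fell at 11 of 18, with 2 higher (3 higher and 11 lower adjusted over the list alone, camera adjusted p = 0.000538, and adjusted p = 0.224 with an estimated correlation). The test called 1203 genes higher and 1655 lower. Quantile normalization gave 1543 and 1420 and read-sum scaling 1498 and 1483. Of the 203 genes called with at least 2-fold, 23 were higher and 180 lower.

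At 24 h with the RXR antagonist, absorptive cell transcripts were far below vehicle, and Tff1, Ivl and the keratin Krt79 above it. Apoa1, the main protein of high-density lipoprotein (chromosome 9, 46228580 to 46230466), fell by 8.48 ± 0.29 (1.64 ± 0.0470 against 773 ± 254 RPKM, adjusted p = 3.96e-11), Apoa4 fell by 6.60 ± 0.23, Sis fell by 5.06 ± 0.18 (10.8 ± 3.48 against 376 ± 121 RPKM), and Adh6a, an alcohol dehydrogenase, fell by 6.22 ± 0.18. Alpi, the intestinal alkaline phosphatase, fell by 3.88 ± 0.11, and Cyp3a11 fell by 6.92 ± 0.25. Tff1, a mucosal trefoil peptide (chromosome 17, 31161395 to 31165277), rose by 4.32 ± 0.10 (725 ± 20.8 against 35.8 ± 0.886 RPKM, adjusted p = 1.03e-12), Ivl by 3.60 ± 0.17, Krt79 by 3.60 ± 0.10 and Trim29 by 3.41 ± 0.15. Lyz1 fell by 2.26 ± 0.20 and Olfm4 fell by 2.41 ± 0.26. Muc2 (0.12 ± 0.11, adjusted p = 0.384) and Chga, a granin of enteroendocrine cells (0.17 ± 0.12, adjusted p = 0.229), were not called. Cyp1a1 was still 3.32 ± 0.11 above vehicle, and Pdk4 0.93 ± 0.075.

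As groups at 24 h with the antagonist, 41 of 43 enterocyte markers fell and 2 rose (2 higher and 41 lower adjusted over the list alone, median -3.71, camera adjusted p = 1.39e-21, and adjusted p = 0.161 with an estimated correlation). Paneth cell markers fell at 16 and rose at 1 of 20 (1 higher and 16 lower adjusted over the list alone, median -0.96, camera adjusted p = 0.00584, and adjusted p = 0.483 with an estimated correlation). Goblet cell markers were not called as a list, with 10 higher and 2 lower of 20 (10 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.0658, and adjusted p = 0.531 with an estimated correlation). Genes of fetal-like and regenerative epithelium rose at 23 and fell at 4 of 32 (24 higher and 4 lower adjusted over the list alone, median 0.77, camera adjusted p = 1.74e-06, and adjusted p = 0.304 with an estimated correlation). Immediate early genes rose at 16 of 17 (16 higher adjusted over the list alone, camera adjusted p = 9.91e-06, and adjusted p = 0.161 with an estimated correlation). Cholesterol synthesis genes rose at 19 and fell at 2 of 25 (19 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.000136, and adjusted p = 0.0595 with an estimated correlation). Cell cycle genes fell at 33 and rose at 1 of 35 (1 higher and 33 lower adjusted over the list alone, camera adjusted p = 6.18e-09, and adjusted p = 0.193 with an estimated correlation). Genes of retinoid uptake, storage and synthesis fell at 14 and rose at 4 of 18 (4 higher and 14 lower adjusted over the list alone, camera adjusted p = 0.000186, and adjusted p = 0.161 with an estimated correlation). The test called 3535 genes higher and 3452 lower, 965 by at least 2-fold (288 higher, 677 lower). Quantile normalization gave 4248 and 2840, and read-sum scaling 3126 and 3891. Because the antagonist was given at 5 µM and the retinoic acids at 10 µM, the sizes of their effects are not matched by dose.

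The antagonist's effect also changed between 6 h and 24 h. It was larger at 24 h by 3.58 ± 0.13 at Tff1 (adjusted p = 3.27e-09) and 2.82 ± 0.24 at Ivl, and lay further below vehicle at Apoa1 (-6.33 ± 0.41, adjusted p = 1.86e-07) and Cyp3a11 (-5.68 ± 0.35). Enterocyte markers had lower effects at 24 h at 41 and higher at 1 of 43 (1 higher and 41 lower adjusted over the list alone, camera adjusted p = 3.00e-29, and adjusted p = 0.1196 with an estimated correlation). Cholesterol synthesis genes had higher effects at 21 of 25 (21 higher adjusted over the list alone, median 0.43, camera adjusted p = 7.04e-09, and adjusted p = 0.0107 with an estimated correlation). In all, 3988 genes differed, 2115 higher at 24 h and 1873 lower, and 533 by at least 2-fold (104 higher, 429 lower). Quantile normalization gave 2336 and 1630, and read-sum scaling 1579 and 2379.

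**Figure D3:**
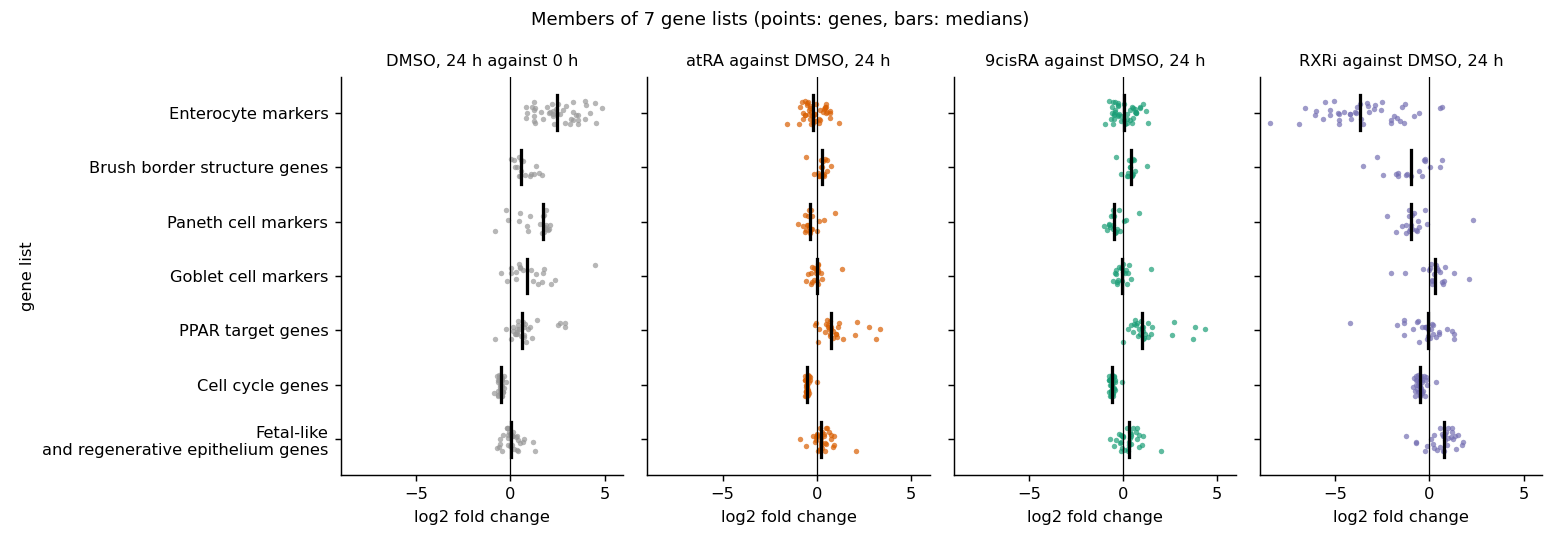
Log2 fold changes of the members of 7 gene lists in 4 comparisons, with points for genes and bars for medians. The median of the enterocyte markers was 2.48 in DMSO at 24 h against 0 h and -3.71 with the RXR antagonist against DMSO at 24 h.

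**Figure D4:**
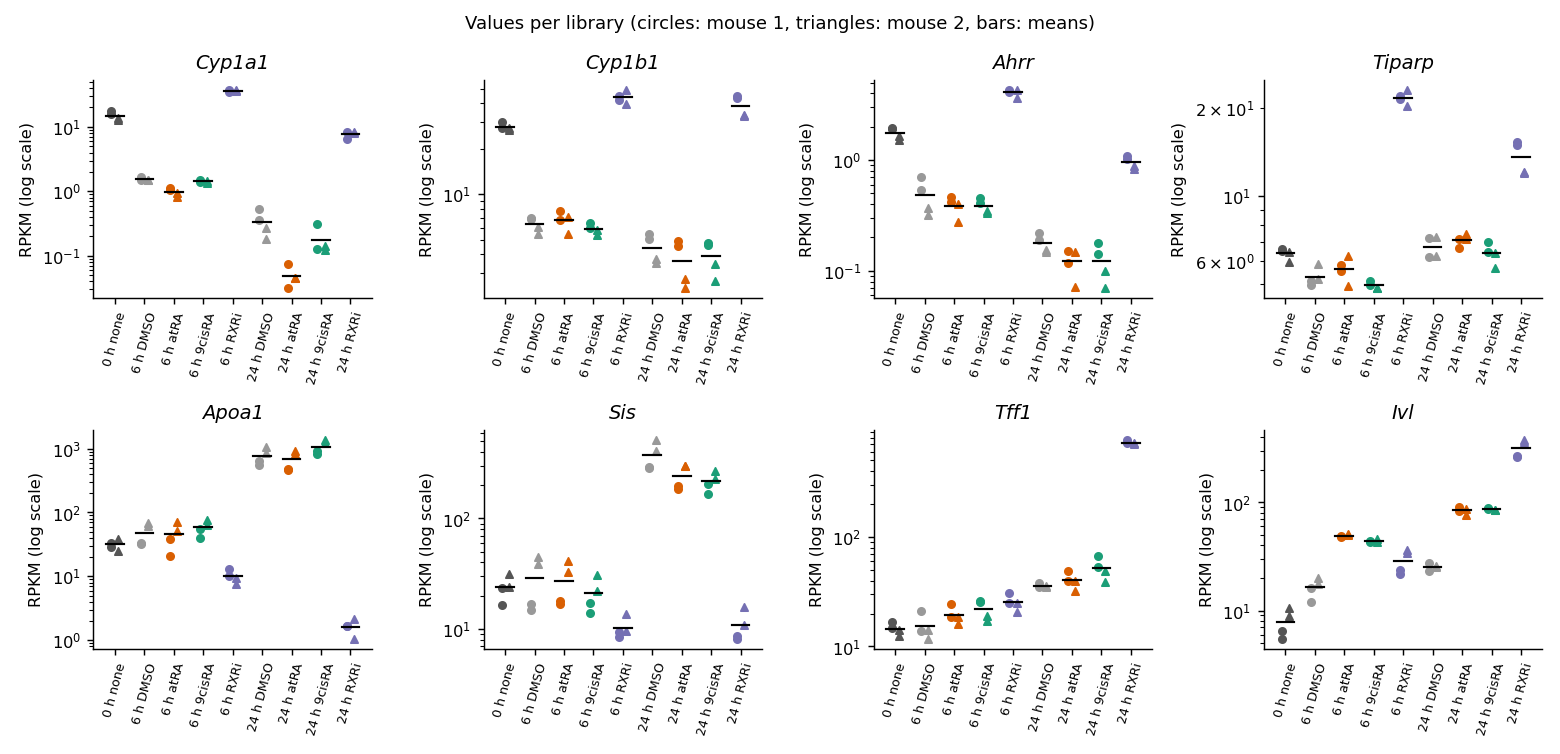
RPKM of 8 genes in each of the 36 libraries on a log scale, with circles for mouse 1, triangles for mouse 2 and bars for condition means. Cyp1a1 averaged 36.6 ± 0.660 RPKM with the RXR antagonist and 1.53 ± 0.0587 RPKM with DMSO at 6 h (mean ± SD over 2 mice).

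The isomers' called genes overlapped widely. At 6 h, 253 genes rose with both and 122 fell with both, where 15.9 and 6.42 would be shared by independent lists, and 0 genes called by limma for both went in opposite directions (2366 genes with atRA and 2384 with 9cisRA had an unadjusted p below 0.05). Fold changes correlated across genes at Pearson r = 0.708, against 0.4996 simulated for unchanged groups that share the vehicle libraries, and genes are not independent replicates. With the vehicle libraries split so that the isomers shared none, r was 0.391 (384 genes the same way and 27 in opposite ways), or 0.683 with the split exchanged (310 and 0). Without the mouse block, 144 genes moved the same way with both isomers at 6 h, against 375 with it. At 24 h, 1977 genes rose and 1896 fell with both isomers, against 538 and 496 for independent lists. There, 1 gene went in opposite directions (Asns, asparagine synthetase, picked out after its values were seen, at 0.19 ± 0.044 with atRA and -0.12 ± 0.044 with 9cisRA), and r was 0.927, or 0.873 with split vehicle libraries. Correlations of the antagonist with the retinoic acids were lower. Simulated unchanged groups that share vehicle libraries gave r of 0.499 to 0.5017, which is no floor where real changes add variance. The covariance of the antagonist's fold changes with those of atRA was 0.00527 at 6 h (0.00380 simulated) and 0.0526 at 24 h (0.00381). With those of 9cisRA it was 0.00444 (0.00378) and 0.0490 (0.00382). At 6 h, 155 genes moved the same way with atRA and the antagonist and 153 in opposite ways (r = 0.109), where independent lists would give 64.4 and 68.6. With split vehicle libraries these were 242 and 271 (r = -0.0094), and with the split exchanged 110 and 122 (r = 0.0793). Without the mouse block 42 moved the same way. For 9cisRA and the antagonist they were 273 and 266 (r = 0.0783), against 110.4 and 119 for independent lists. The split gave 232 and 274 (r = 0.0289), and its exchange 248 and 292 (r = -0.00101), and 101 moved the same way without the mouse block. At 24 h, 2616 genes moved the same way with atRA and the antagonist and 685 in opposite ways (r = 0.235), against 1327 and 1326 for independent lists. The split gave 2403 and 763 (r = 0.190), and its exchange 2439 and 657 (r = 0.246). For 9cisRA they were 2952 and 910 (r = 0.195), against 1675 and 1674. The split gave 2787 and 958 (r = 0.155), and its exchange 2814 and 873 (r = 0.206). Pdk4 rose with all 3 compounds at 24 h, by 3.37 ± 0.075, 4.32 ± 0.075 and 0.93 ± 0.075 with atRA, 9cisRA and the antagonist.

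None of the 4 tested retinoid receptor genes was called with the retinoic acids at 6 h. Rara, the retinoic acid receptor alpha, stood at -0.011 ± 0.062 with atRA and 0.072 ± 0.062 with 9cisRA, and Rarg at 0.12 ± 0.079 and 0.17 ± 0.079. Rxra, the retinoid X receptor alpha, just missed the threshold with atRA (-0.22 ± 0.058, adjusted p = 0.0514) and stood at -0.18 ± 0.058 with 9cisRA (adjusted p = 0.0784), and Rxrb at -0.11 ± 0.081 and 0.000035 ± 0.081. At 24 h, Rara rose by 0.22 ± 0.062 with atRA (adjusted p = 0.0143) and 0.43 ± 0.062 with 9cisRA (adjusted p = 0.000117), and Rarg by 0.29 ± 0.079 (adjusted p = 0.0117) and 0.29 ± 0.079 (adjusted p = 0.00861). Of these, the call of Rara with atRA and both calls of Rarg ended without the mouse block (adjusted p = 0.112, 0.102 and 0.0810). Rxra rose with 9cisRA at 24 h by 0.17 ± 0.058 (adjusted p = 0.0274), a call that ended without either mouse (adjusted p = 0.158 and 0.0766), with read-sum scaling (0.04, adjusted p = 0.514) and without 1 library in 3 cases. With the antagonist, Rara fell by 0.28 ± 0.062 at 6 h (adjusted p = 0.00458), a call that ended without the mouse block (adjusted p = 0.0661) and without mouse 1 (0.291). Rarg rose with it by 0.49 ± 0.079 at 6 h and 0.86 ± 0.079 at 24 h (adjusted p = 6.42e-07), and Rxra changed by -0.34 ± 0.058 (adjusted p = 0.000787) and -0.34 ± 0.058 (adjusted p = 0.000176). Rxrb was called at neither time (-0.039 ± 0.081 and -0.063 ± 0.081). Cyp26a1, Rarb, Rxrg, Dclk1 and Cyp24a1 were not analysed here, and Lgr5 was too low to be tested.

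Several groups were called in none of the 14 comparisons. The smallest camera adjusted p was 0.0697 for 18 p53 target genes, 0.278 for 11 heat shock genes, 0.123 for 12 enteroendocrine markers, 0.0885 for 7 M cell markers and 0.0673 for 5 immune cell markers. Retinoid receptors, VDR target genes, tuft cell markers and markers of stomach and colon had 4 tested members each, fibroblast markers 3 and endothelial markers 2, too few for a list test.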

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

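The tests of explanations below were all chosen after the results they concern had been seen, while the check for distant libraries and the comparison of effects between times were fixed beforehand.

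The effect of a compound differed between 6 h and 24 h, by a test of the difference itself, at 1947 genes for atRA, 2040 for 9cisRA and 3988 for the RXR antagonist.

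The rise of Cyp1a1, Cyp1b1, Ahrr and Tiparp with the RXR antagonist at 6 h was weighed first. Retention of the level before the medium change as the whole cause was argued against at 6 h. There the 4 genes stood at a median of 1.15 log2 above 0 h (largest SE 0.15). Part of the gap to vehicle was a fall in vehicle from 0 h (Cyp1a1 -2.92, Cyp1b1 -2.06, Ahrr -1.22, Tiparp -0.25), so a partly missing decline remains possible. At 24 h with the antagonist, Cyp1a1 and Ahrr lay below their 0 h values in all libraries, and Cyp1b1 and Tiparp above. The rise was large in both mice, with 1.88 as the smallest value of a mouse over the 4 genes. The rule for the highest genes asked for a call, a large change and the same sign in both mice. It thus left little room for a rise in a single mouse, and this check adds little. A list of 11 aryl hydrocarbon receptor target genes was written after these 4 had been seen, and of its 5 other tested members 4 were called higher (Nqo1 0.29, Ugt1a6a 0.23, Ugt1a7c 0.22, Aldh3a1 0.96) and 1 lower (Xdh -0.80), although Ugt1a6a and Ugt1a7c share exons of 1 locus, so their reads are uncertain and they are not independent members. With 9cisRA at 6 h, where Cyp1a1 was not called (-0.078), 3 of these 4 were called higher as well (Ugt1a6a 0.30, Ugt1a7c 0.32, Aldh3a1 1.35), and with the antagonist at 24 h Nqo1, Ugt1a6a and Ugt1a7c were called lower (-0.52, -0.75 and -0.65) while Cyp1a1 was 3.32 higher. The other members thus decide nothing, and activation of this receptor by the antagonist or its formulation stays open.

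The fall of enterocyte markers with the antagonist at 24 h was weighed next. A mere absence of the vehicle rise was argued against, since 34 of 43 markers were called below their 0 h level and 9 above. With read-sum scaling the median of the markers was -3.74. That scaling moved the median of all genes just to -0.041, so it could not have brought the markers near 0. It shows that the choice between these 2 scalings did not make the fall, and it tests little else. A loss of enterocytes alone, with other cells unchanged, was argued against by 16 of 20 Paneth cell markers that were also lower and 1 that was higher. The Paneth cell list was called in no comparison with an estimated correlation, though. Goblet cell markers were not called as a list against vehicle, with more members higher than lower, so the argument rests on Paneth cell markers. A block of differentiation in all cell types was argued against by goblet cell markers, 17 higher and 1 lower of 20 than at 0 h (median 1.43). Paneth cell markers were 11 higher and 4 lower of 20 than at 0 h. A change in several cell types may remain, as a hypothesis from the same data that was not tested.

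The gap between the isomers at Fabp6 at 24 h was weighed last. Too few reads were argued against, since the atRA libraries held 55 to 140 reads of Fabp6 and the 9cisRA libraries 2 to 5. The gap was large in both mice, at -3.02 in the mouse nearer 0. The naming rule asked for a call, a large change and the same sign in both mice. It thus left little room for a gap in a single mouse, and that check adds little. As a group, the remaining 6 FXR target genes were lower with 9cisRA at an adjusted p of 0.0447 with an estimated correlation (median -0.55), yet just 2 of them were called lower one by one, and adjusted over the list alone 4 were lower and 1 higher. A weaker FXR-type response at some of these genes could be part of it, as a hypothesis close to the threshold.

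A library stood far from the 3 others of its condition, by the gap to its neighbor as a share of the range, in 9 of 315 groups of 4 libraries tested, where chance gives about 15.8 (5%). That 5% is a rough guide, as it takes the 4 libraries as alike, whereas they are 2 duplicates of each of 2 mice. For Rxra with DMSO at 6 h the share was 0.851 (mouse 2, duplicate 2, 13.3 RPKM against 14.7 to 15.0 RPKM). For Ascl2 it was 0.951 with 9cisRA at 6 h (mouse 2, duplicate 2, 1.498 RPKM against 2.41 to 2.47 RPKM) and 0.866 with the antagonist at 24 h (mouse 2, duplicate 1, 1.54 RPKM against 2.13 to 2.24 RPKM). For Lyz1 with DMSO at 24 h it was 0.910 (mouse 2, duplicate 2, 31.7 RPKM against 29.1 to 29.3 RPKM), and for Alpi with 9cisRA at 24 h 0.886 (mouse 2, duplicate 1, 974 RPKM against 885 to 895 RPKM). For Cyr61 with 9cisRA at 6 h it was 0.867 (mouse 1, duplicate 1, 20.7 RPKM against 18.9 to 19.1 RPKM) and for Hmgcs1 at 0 h 0.933 (mouse 1, duplicate 1, 84.0 RPKM against 95.3 to 96.1 RPKM). The number of genes at 0 with 9cisRA at 24 h gave 0.833 (mouse 2, duplicate 1, 11 genes against 5 to 6), and the median RPKM with atRA at 6 h gave 0.857 (mouse 2, duplicate 1, 8.84 RPKM against 8.90 to 8.92 RPKM).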

How the results depend on the processing

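The alternatives were planned, except read-sum scaling, voom on recovered reads and the exchanged split of the DMSO libraries, which were chosen after the data were seen. The totals of called genes for 9cisRA and the antagonist against DMSO at 24 h, and in the 3 DMSO comparisons between times, stayed within 1.5 times under every alternative except the 2-fold threshold. Other pseudocounts and filters, read-sum scaling and the robust prior moved no total by more than 1.5 times, although read-sum scaling shifted the balance of higher and lower genes. Of 1385 gene results, a pseudocount of 0.1 kept 1364 on their side of the threshold, no filter 1376, read-sum scaling 1316 of 1371 and quantile normalization 1316 of 1385. Fewer were kept without the mouse block (1239, with 146 calls lost), without mouse 1 (1260, with 102 lost) and without mouse 2 (1276, with 62 lost). For gene lists, 288 of 297 results kept their side with quantile normalization. Median-of-ratios scaling nearly repeats the scaling of the deposited values, so that alternative tests little. Of 13696 gene results with 1 library left out, 187 lost their call and 183 gained one, and 75 of the 930 called gene results lost the call without at least 1 library. Depth limits genes of few reads. Those that reached 1 RPKM in fewer than 4 libraries were not tested, yet tested genes can lie below 1 RPKM in a comparison, such as Cyp26b1 with atRA at 6 h (0.338 against 0.0318 RPKM), and n = 2 mice limits what holds beyond these animals.

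Quantile normalization reversed 1 result, Clu in DMSO at 24 h against 0 h, to -0.11 (adjusted p = 0.168), and it left 35 calls between the isomers at 24 h. The cause was not tested for either.

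Without the mouse block, the fit called 177 genes for atRA at 6 h, 416 for 9cisRA at 6 h, 40 and 10 between the isomers at 6 h and 24 h, and 983 and 1073 for the changes of the atRA and 9cisRA effects between times. Shared genes at 6 h in that unblocked fit numbered 144 for atRA and 9cisRA, 42 for atRA and the antagonist and 101 for 9cisRA and the antagonist. The cause was not tested, although the block takes up the differences between mice.

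Treating duplicates as samples raised the same 6 totals, in that order, because duplicates of a culture then count as replicates. The values were 1341, 1602, 562, 292, 3197 and 3267 with 36 separate libraries, and 1289, 1564, 521, 260, 3144 and 3213 with a block of mouse and duplicate number. With voom on recovered reads they were 1280, 1631, 534, 338, 3152 and 3255. With an estimated duplicate correlation, atRA at 6 h reached 975 and the isomers 307 and 186, and with only the groups of the times compared these were 895, 305 and 107, where the cause was not tested.

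A stricter threshold gave fewer calls by construction. At an adjusted p below 0.01 there were 228 for atRA, 450 for 9cisRA and 1754 for the antagonist at 6 h, 2666 for atRA at 24 h, 43 and 18 between the isomers, and 667, 794 and 2577 for the changes between times. With at least 2-fold there were 14, 37 and 203 at 6 h and 118, 160 and 965 at 24 h for atRA, 9cisRA and the antagonist, 6 and 4 between the isomers, 78, 572 and 571 in DMSO (6 h and 24 h against 0 h, 24 h against 6 h) and 56, 42 and 533 for the changes between times.

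Leaving out single libraries or a whole mouse gave ranges of 229 to 1061 for atRA at 6 h, 43 to 695 and 49 to 112 between the isomers at 6 h and 24 h, 2766 to 4421 for atRA at 24 h, and 635 to 2424 and 1147 to 2455 for the changes of the atRA and 9cisRA effects. The other totals stayed within 1.5 times in these fits. The lone library of a culture, or the duplicates of 1 mouse, were then assumed to vary like the other groups, and the cause was not tested. With 1 library left out, the extremes for atRA and between the isomers at 6 h came without either atRA library of mouse 2. Among all duplicate pairs, these libraries had the largest chi-square of reads and the lowest correlation. Whether their discordance set those extremes was not tested.

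Camera with an estimated correlation left 28 list calls, and the cause was not tested. With DMSO libraries split between compounds, atRA and the antagonist at 6 h shared 242 genes with the same direction, beside 271 with opposite directions, and 110 and 122 with the split exchanged. The cause was not tested.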

Other observations

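The comparison of the antagonist at 24 h with 0 h and the fits of treatment by mouse were chosen after the data had been seen, and the other values here come from planned fits.

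Against the 0 h cultures, those with the RXR antagonist at 24 h had less of most enterocyte markers (34 of 43 lower, 9 higher) and more Tff1, Ivl and Krt79. Apoa1 stood at -3.92 log2 relative to 0 h, Cyp3a11 at -3.76, Alpi at -1.82, Apoa4 at -1.71 and Sis at -1.12, while the fatty acid binding protein Fabp1 stood at 1.55. Tff1 was 5.61 higher, Ivl 5.28 and Krt79 3.95, while Lyz1 stood at -1.21 (adjusted p = 0.000125) and Olfm4 was not called (0.38, adjusted p = 0.213). Muc2 was 2.47 higher and goblet cell markers were higher at 17 and lower at 1 of 20, at a median of 1.43. With vehicle alone, Muc2 was 2.35 higher and the markers higher at 16 and lower at 2 of 20, at a median of 0.90. Paneth cell markers were higher at 11 and lower at 4 of 20, against 17 and 2 with vehicle, and all 35 cell cycle genes were lower. Brush border genes were higher at 5 and lower at 8 of 17 (median -0.14), genes of fetal-like and regenerative epithelium higher at 24 and lower at 5 of 32, and stem cell markers higher at 3 and lower at 12 of 19. Genes of retinoid uptake, storage and synthesis were higher at 5 and lower at 9 of 18. The limma test called 4104 genes higher and 3944 lower than at 0 h. In vehicle cultures, 553 genes were at least 2-fold higher at 24 h than at 0 h. Of these, 487 were lower and 32 higher with the antagonist than with vehicle at 24 h. The vehicle libraries at 24 h served in both comparisons, so part of that count may come from the selection. Against 0 h, 197 of the 553 were called higher, 240 lower and 116 not at all.

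Smaller groups moved as well. Cytosolic ribosomal protein genes fell in vehicle by 24 h at 30 of 32 (30 lower adjusted over the list alone, median -0.31, camera adjusted p = 1.61e-07, and adjusted p = 0.226 with an estimated correlation). This list, fixed as a measure of quality, was called by camera in 8 of the 14 comparisons, and in 0 with an estimated correlation. Genes of the NRF2 and xenobiotic response rose with 9cisRA at 6 h at 12 of 25 (15 higher adjusted over the list alone, camera adjusted p = 1.30e-09, and adjusted p = 0.0833 with an estimated correlation). YAP target genes rose in vehicle by 6 h at 14 and fell at 1 of 19 (15 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.000242, and adjusted p = 0.325 with an estimated correlation). Glycolysis and hypoxia genes rose with the antagonist at 24 h at 12 and fell at 3 of 23 (12 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.00695, and adjusted p = 0.447 with an estimated correlation), and unfolded protein response genes rose with it at 6 h at 7 of 20 (7 higher adjusted over the list alone, camera adjusted p = 0.000406, and adjusted p = 0.113 with an estimated correlation). NF-kB target genes rose with atRA at 24 h at 9 and fell at 1 of 12 (9 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.00100, and adjusted p = 0.0515 with an estimated correlation).

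The mice differed at 2312 genes over all conditions, 3 of them by over 2-fold, and these 3 were picked out after their values were seen. Each mouse gave 1 culture, so the spread behind these calls is between conditions and not between animals. The animal cannot be told apart from its culture or handling here. Ang4, an antimicrobial ribonuclease of Paneth cells, was 1.23 ± 0.088 log2 higher in mouse 2 (11.6 against 4.66 RPKM), and Defa3, a defensin with near-identical copies that make its assignment uncertain, 1.03 ± 0.13 higher (49.5 against 26.3 RPKM). Rps4l, a ribosomal protein gene, was lower in mouse 2 at -1.03 ± 0.055 (11.2 against 23.3 RPKM). In limma fits of treatment by mouse, 0 to 4 genes per comparison had effects that differed between the mice, and none of these had opposite signs in them. At an unadjusted p below 0.05 there were 505 to 1332, where 5% of the 11361 tested genes would reach it with no difference. Each mouse gave 1 culture, so these fits had no repeat cultures of a mouse to measure spread from. Over all called genes, 99.94% shared their sign in both mice with the antagonist at 24 h and 99.96% in DMSO at 24 h against 0 h. In the other comparisons it was 100%.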
